A study of Mus musculus with 15 samples.

How the data were processed

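RNA was measured in fibroblasts sorted from the thymus of young male wild-type mice that were untreated, or 1 or 3 days after 425 rad of irradiation, with 5 libraries per group, per the labels. Thymi were digested with Liberase TH and DNase, cells were sorted into lysis buffer, mRNA was captured on oligo-dT beads and MARS-seq libraries were sequenced, per the labels' protocols. The submitters' processing notes name bcl2fastq, cutadapt, STAR 2.5.2b, HTSeq and DESeq2, with alignment to mm10. The deposited table held 12763 genes and 15 libraries, with raw UMI counts that the authors had not scaled. The authors' normalized columns hold a signal, counts divided by a size factor per library, per the file headers and a check of their ratio to the raw columns. The authors' regularized columns and fold changes are on the log2 scale, per the file headers, and each fold change puts the group named first over the other. The deposited p-value columns hold the authors' p and adjusted p for each comparison. Every gene in the table had at least 6 UMIs in some library, and no mitochondrially encoded gene was analysed here.

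Groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. All values below were computed from the raw UMI counts, and the authors' other columns served only for the stated comparison. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes were filtered with filterByExpr, which kept 10207, and libraries were scaled with TMM. A single edgeR quasi-likelihood model with robust dispersion was fitted to all 15 libraries with group as the factor, and the biological coefficient of variation was 0.201. The 3 comparisons were day 1 against untreated, day 3 against untreated and day 3 against day 1, each with the Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The SE of a log2 change was its size divided by the square root of the F statistic. Library totals ran from 740169 to 3750214 UMIs. In simulated data with 200 changed genes among 10207, edgeR recovered 23.9%, 58.2% and 93.9% of changes of 1.5, 2 and 4 times at the day 1 comparison's depth, 28.4%, 64.2% and 98.5% at day 3, and 19.4%, 70.1% and 95.5% for day 3 against day 1, with 5 or 6 unchanged genes called. These rates hold for that share of changed genes, balanced in direction. The data had 46.21%, 18.45% and 32.67% of genes called, so recovery there can differ.

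Of 34 gene lists written from general knowledge, 20 held processes and 14 held cell type markers. Those with at least 3 tested genes, 30 in number, were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Lists overlapped, with 9 of 49 matrix genes and 9 of 19 identity genes also in another list. Summed CPM of marker lists and library measures were compared with exact permutation tests over all 252 assignments of 5 against 5, for which the smallest p is 0.00794, adjusted over 57 tests. Genes were named by a rule: per comparison, the 6 largest rises and 6 largest falls among called genes with a mean of at least 20 CPM in a group and no overlap between groups, up to 3 called members of smallest p from each process list in order of the list's camera p, and a fixed set with Cdkn1a, Mdm2, Mki67, Il33, Tslp, Fgf7, Bmp4, Cxcl12, Col1a1 and the sort markers. Growth factor and type-2 lists were kept out of that order at day 3 because of the series title. Genes in the closing section outside the rule were chosen after their values were seen, as was Ccl22's count in single libraries. The overlap of the day 1 and day 3 calls, which share the untreated libraries, was set beside 20 simulated data sets of unchanged groups and 20 splits of the untreated libraries.

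Alternatives were DESeq2, limma voom with quality weights, RLE or total-count scaling, no filter or at least 10 counts in 5 libraries, only the compared groups, the replicate number as a block, counts thinned to 740169 per library, a threshold of 1.5 times with glmTreat, leaving out each library in turn, fry, and total counts for the lists. The gene list tests without day 1 replicate 1 were added after seeing the data. Gene coordinates are those of GENCODE vM21 on GRCm38. Reads were not at hand, so mapping, barcode errors and sequence bias were not examined.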

Results

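The data came from fibroblasts of the mouse thymus, the organ in which T cells mature and which shrinks and regrows after irradiation. Young male wild-type mice received 425 rad, a dose below the lethal one, or were left untreated, and fibroblasts were sorted 1 or 3 days later. The series title links these cells and tuft cells, a chemosensory epithelial type, to type-2 immunity during regrowth. Each of the 3 groups held 5 libraries, 15 in all, made with MARS-seq, which counts the 3' ends of captured mRNA by unique molecular identifiers (UMIs). Library totals ran from 1102176 to 2661621 UMIs in untreated samples, from 740169 to 2638344 at day 1 and from 1967148 to 3750214 at day 3. Gene levels below are means ± SD of CPM, UMIs scaled to the TMM-adjusted library total, with n = 5 per group, and log2 changes are given ± SE. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples.

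The sort gate required the surface proteins CD34 and PDGFRα and excluded CD45, carried by leukocytes, and CD31, carried by endothelium, while the label also gave EpCAM, an epithelial protein, as positive. Pdgfra was at 310.2 ± 40.2 CPM and Cd34 at 1571 ± 87.8 CPM in untreated samples. Epcam transcripts summed to 11 UMIs over the untreated libraries, 10 at day 1 and 10 at day 3. Pecam1, which encodes CD31, gave 35, 59 and 47 UMIs in the same order, and Ptprc, which encodes CD45, gave 35, 38 and 9. Epcam, Pecam1 and Ptprc fell below the expression filter. Il7 was not analysed here. The first principal component held 46.8% of the variance and ordered untreated (-47.98 to -32.64), day 3 (-15.86 to -7.32) and day 1 libraries (30.35 to 86.56). Day 1 replicate 1, the library with the fewest UMIs, stood apart on the second component at 65.97, against -27.3 to -23.98 for the other day 1 libraries.

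The first comparison asked what changed 1 day after irradiation. Interferon-stimulated genes, the antiviral program that interferons switch on, rose in all 45 members tested. Isg15, a ubiquitin-like modifier, went from 168 ± 33.7 to 5181 ± 806 CPM, and the transcription factor Irf7, which amplifies type I interferon production, from 139 ± 17.2 to 3364 ± 690.3 CPM. The p53 targets that stop the cell cycle and remove damaged cells rose in 30 of 42 members. Of 49 matrix genes 34 fell, of 19 fibroblast identity genes 14 fell, and 15 of 18 macrophage and dendritic cell markers and 10 of 10 mesothelial markers were higher. These 4 lists did not pass with an estimated correlation (camera adjusted p = 0.164, 0.16, 0.164 and 0.373 in that order). In all, edgeR called 4717 of 10207 genes, 2355 higher and 2362 lower, of which 1084 and 1128 changed at least 2-fold.

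The interferon-stimulated list had a median log2 change of 2.80 (camera adjusted p = 6.9e-32, and adjusted p = 0.012 with an estimated correlation), with the same 45 members called when adjusted over the list alone. Isg15 changed by 4.95 ± 0.22, Irf7 by 4.59 ± 0.18 and the nucleic acid sensor Zbp1 by 4.03 ± 0.17 on the log2 scale, each with an edgeR adjusted p of 5.1e-13 or below. Genes of MHC class I antigen presentation, which displays cytosolic peptides to CD8 T cells, rose in 16 of 18 members, 17 adjusted over the list alone, with 2 not called (camera adjusted p = 3.3e-10, and adjusted p = 0.0161 with an estimated correlation). The peptide transporter gene Tap1 changed by 2.499 ± 0.14, the class I transactivator Nlrc5 by 3.73 ± 0.21 and the immunoproteasome subunit Psmb8 by 2.42 ± 0.16, with edgeR adjusted p values up to 1.3e-10. Inflammatory cytokines and chemokines rose in 24 of 30 members and fell in 1 (camera adjusted p = 3.6e-09). Adjusted over the list alone, the counts were 26 and 1. The list did not pass at adjusted p = 0.164 with an estimated correlation. Saa3, an acute-phase protein, rose from 393 ± 385 to 26362 ± 8056 CPM, Lcn2, which binds bacterial siderophores, from 68.5 ± 64.3 to 5582 ± 2449, Csf3, the granulocyte growth factor, from 3.50 ± 3.47 to 166 ± 90.1, and the chemokine Cxcl16 from 62.5 ± 14.4 to 181 ± 36.8, with edgeR adjusted p values up to 3.1e-06. Untreated replicate 5 held 1077 CPM of Saa3 and 183 of Lcn2, and without it the log2 changes of Saa3, Lcn2 and Csf3 were 6.89, 7.14 and 6.41 in place of 6.07, 6.35 and 5.80. Complement genes rose in 7 of 12 members and fell in 2, the same counts adjusted over the list alone (camera adjusted p = 0.0243, and adjusted p = 0.328 with an estimated correlation). With total-count scaling 4 complement genes were higher and 3 lower. Cfb, a protease of the alternative pathway, changed by 2.77 ± 0.17, C2 by 2.03 ± 0.20 and C4b, whose reads can be shared with the paralog C4a, by 2.34 ± 0.24, with edgeR adjusted p values up to 1.3e-07. Beside these immune groups, the summed level of macrophage and dendritic cell markers, in CPM of total counts, was 1461 ± 270.3 at day 1 against 650.4 ± 317 in untreated samples (exact permutation p = 0.00794, adjusted p = 0.0302, n = 5 per group).

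**Figure D1:**
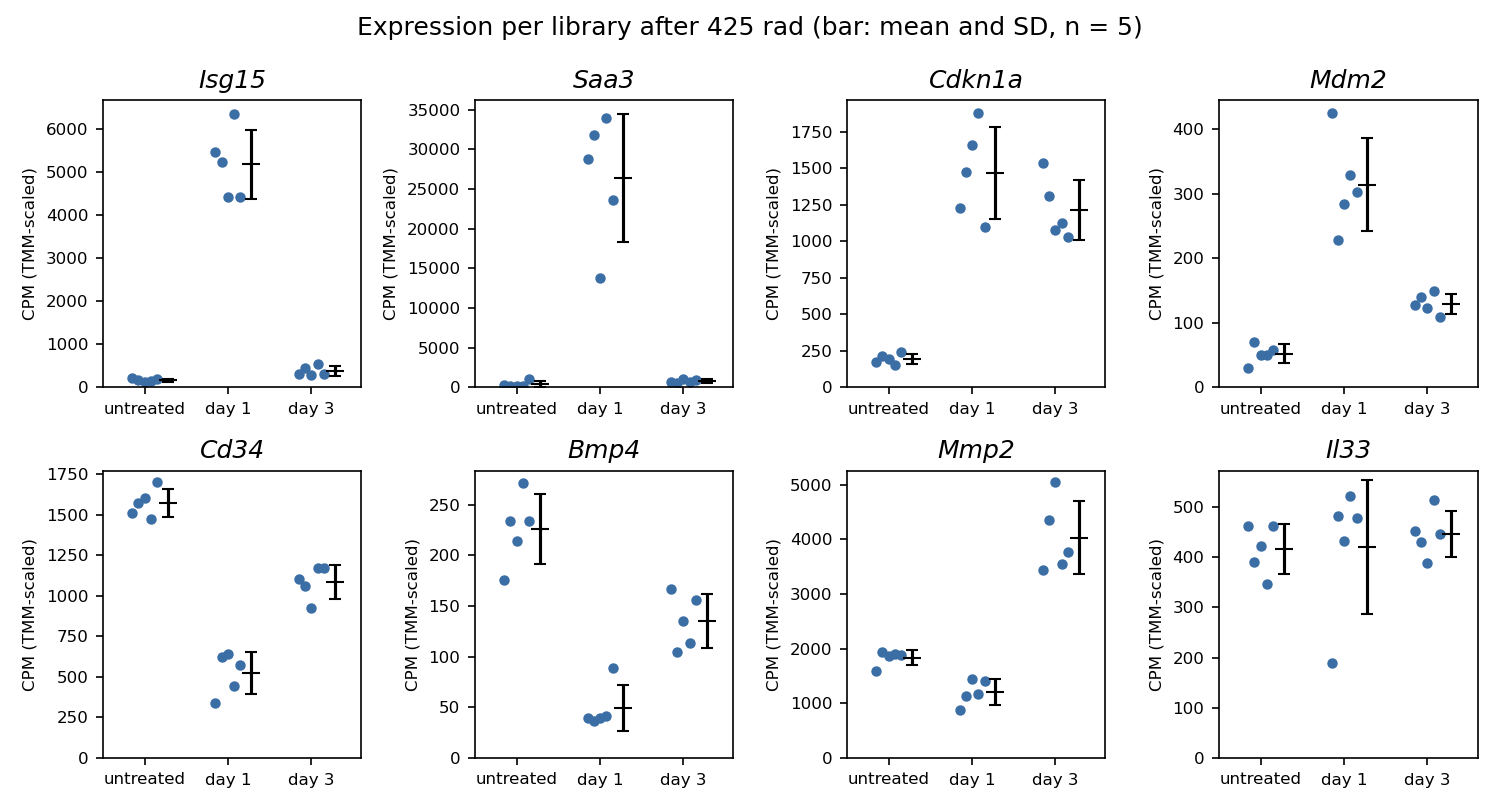
TMM-scaled CPM of 8 genes in each of the 15 libraries, by group, with the mean and SD (n = 5) drawn as bars. Isg15 rose from 168 to 5181 CPM at day 1 and was at 381 CPM at day 3, Cdkn1a was at 1467 and 1215 CPM at days 1 and 3, Mmp2 was highest at day 3, and Il33 means lay between 417 and 446 CPM.

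p53 targets rose in 30 of 42 members and fell in 3, with 9 not called (camera adjusted p = 1.7e-09, and adjusted p = 1.9e-04 with an estimated correlation). The counts were 31 and 3 when adjusted over the list alone. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose from 194 ± 35.05 to 1467 ± 316 CPM, and Mdm2, the ubiquitin ligase that degrades p53, from 52.00 ± 14.6 to 314 ± 72.1 CPM. Psrc1 changed by 3.54 ± 0.25 on the log2 scale, and the 3 genes had edgeR adjusted p values up to 1.0e-09. Immediate-early and heat-shock genes rose in 22 of 29 members, 23 adjusted over the list alone (camera adjusted p = 3.2e-07, and adjusted p = 0.117 with an estimated correlation). Among them, the AP-1 subunit Fosl1 changed by 2.40 ± 0.25, Ier3 by 1.82 ± 0.21 and the zinc finger factor Egr2 by 1.73 ± 0.22, with edgeR adjusted p values up to 1.5e-06. Unfolded protein response genes, which raise folding capacity in the endoplasmic reticulum, rose in 12 of 20 and fell in 1, unchanged as counts adjusted over the list alone (camera adjusted p = 8.4e-04, and adjusted p = 0.0489 with an estimated correlation). The chaperone Calr changed by 1.20 ± 0.14 and the disulfide isomerase Pdia6 by 1.00 ± 0.13, while Sel1l, part of the machinery that removes misfolded proteins, changed by -0.90 ± 0.14, with edgeR adjusted p values up to 2.1e-05. NRF2 and antioxidant genes rose in 11 of 20 and fell in 4, the same over the list alone, without passing as a list (camera adjusted p = 0.0745), though the list passed without day 1 replicate 1 (camera adjusted p = 0.0268, up to 0.399 over the other alternatives with camera). Hmox1, which degrades heme, changed by 1.81 ± 0.20, thioredoxin Txn1 by 1.31 ± 0.16 and Gclc, the first enzyme of glutathione synthesis, by 1.35 ± 0.21, with edgeR adjusted p values up to 1.9e-05. Without day 1 replicate 1 the p53 targets counted 30 higher and 1 lower and the unfolded protein response genes 13 and 2. Total-count scaling gave 10 and 2 for the latter and 7 and 5 for NRF2 and antioxidant genes. Immediate-early and heat-shock genes counted 15 higher and 0 lower of 29 with total-count scaling.

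Extracellular matrix genes fell in 34 of 49 members and rose in 3 (camera adjusted p = 5.1e-09). Adjustment over the list alone gave 37 and 3. The list did not pass at adjusted p = 0.164 with an estimated correlation. The collagens Col8a1 and Col14a1 went from 133 ± 23.2 to 16.2 ± 6.21 CPM and from 725 ± 40.2 to 183 ± 39.9 CPM, and the proteoglycan Aspn from 377 ± 47.1 to 57.5 ± 26.5 CPM (edgeR adjusted p values up to 1.9e-09). Col1a1, the main chain of type I collagen, was at 1356 ± 238 and 955 ± 409.8 CPM and was not called (edgeR adjusted p = 0.0836, 0.00758 to 0.188 over the alternatives), but was in 4 of 17 alternatives, among them limma voom (adjusted p = 0.0321), edgeR with total counts (0.0136) and, at a log2 change of -0.73, without day 1 replicate 5. Matrix-degrading enzymes and inhibitors counted 5 higher and 11 lower of 24, the same over the list alone (camera adjusted p = 0.134). The metalloproteinase inhibitor Timp1 rose from 170.4 ± 77.96 to 3728 ± 1467 CPM while its relative Timp2 fell from 2863 ± 276 to 731 ± 199, and the procollagen protease Adamts2 changed by -1.61 ± 0.18 (edgeR adjusted p values up to 2.9e-07). Fibroblast identity genes, 9 of which are in other lists, fell in 14 of 19 and rose in 2 (camera adjusted p = 3.8e-05, and adjusted p = 0.16 with an estimated correlation). With adjustment over the list alone they were 15 and 2. Pdgfra changed by -1.47 ± 0.17 and Cd34 by -1.58 ± 0.16, with edgeR adjusted p values up to 5.1e-07. Markers of parenchymal fibroblasts fell in 10 of 13 and rose in 3 (camera adjusted p = 9.8e-04, and adjusted p = 0.164 with an estimated correlation), the same counts adjusted over the list alone. Examples were Smoc2 at -2.81 ± 0.19, the matricellular Sparcl1 at -2.20 ± 0.19 and lipoprotein lipase Lpl at -2.40 ± 0.24 (edgeR adjusted p values up to 1.1e-07). Markers of adventitial fibroblasts fell in 9 of 16 and rose in 4 (camera adjusted p = 0.0184, and adjusted p = 0.373 with an estimated correlation). Counts adjusted over the list alone were 10 and 4. Among these, Efhd1 changed by -2.93 ± 0.24, the peptidase Dpp4 by -2.77 ± 0.24 and Wnt2 by -2.34 ± 0.22, with edgeR adjusted p values up to 4.2e-08. Beside these fibroblast groups, the summed CPM of the identity list was 41199 ± 9358 at day 1 against 87084 ± 2584 in untreated samples, and day 1 replicate 1 was lowest at 25010 (exact permutation p = 0.00794, adjusted p = 0.0302, n = 5). Total-count scaling gave 1 matrix gene higher and 39 lower.

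Cell cycle genes fell in 8 and rose in 2 of 24 tested, or 7 and 2 adjusted over the list alone, without passing as a list (camera adjusted p = 0.177). Cyclin Ccnd1 changed by -1.65 ± 0.23 and the proliferation antigen Mki67 by -2.40 ± 0.46, while the tubulin Tubb5 changed by 0.70 ± 0.15, with edgeR adjusted p values up to 7.8e-04. Thymic growth and niche factors counted 9 higher and 14 lower of 32 (camera adjusted p = 0.243). Adjusted over the list alone, the counts were 9 and 15. Bmp4, which acts on thymic epithelium, fell from 226 ± 34.6 to 49.2 ± 22.5 CPM, Igf1 from 182 ± 37.2 to 48.00 ± 12.1 and the Wnt antagonist Sfrp1 from 325 ± 98.9 to 77.8 ± 18.3 (edgeR adjusted p values up to 8.1e-08). Fgf7, an epithelial growth factor, changed by -0.68 ± 0.20, and Cxcl12, the chemokine that holds progenitors in the niche, by 1.28 ± 0.26 (edgeR adjusted p = 0.0089 and 6.1e-04). Type-2 immune mediators counted 5 higher and 2 lower of 12, the same over the list alone, with a median of -0.06, a mean of 0.42 and a camera direction upward (camera adjusted p = 0.319). The cytokine signalling inhibitors Socs1 and Cish changed by 2.28 ± 0.22 and 1.97 ± 0.28 and the chemokine Ccl8 by 2.75 ± 0.38, with edgeR adjusted p values up to 2.7e-05. The alarmin Il33 was at 417 ± 49.4 and 420.3 ± 133 CPM and was not called (edgeR adjusted p = 0.938, 0.178 to 0.988 over the alternatives), with a log2 change of 0.21 without day 1 replicate 1. Tslp, an epithelial and stromal cytokine that starts type-2 responses, was at 11.2 ± 2.69 and 8.70 ± 3.74 CPM (edgeR adjusted p = 0.227, 0.04 to 0.469 over the alternatives), with a log2 change of -0.68 and a call without day 1 replicate 5. Cell cycle genes counted 4 higher and 9 lower without day 1 replicate 1 and 1 and 12 with total-count scaling, which gave 5 and 4 for type-2 mediators.

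Among genes whose 5 day 1 and 5 untreated values did not overlap, which chance gives to 0.794% of unchanged genes, the 6 largest rises were in Lcn2, Saa3 and Csf3, given above, and in Gpbar1, a bile acid receptor, Slfn4, an interferon-inducible gene known from myeloid cells, and Oas3, an antiviral synthetase. Their log2 changes were 6.69 ± 0.52, 6.17 ± 0.61 and 5.62 ± 0.31 (edgeR adjusted p values up to 3.7e-07). Untreated libraries held 0 to 0.426 CPM of Gpbar1, 0 to 1.28 of Slfn4 and 1.21 to 3.40 of Oas3, so the sizes of these rises rest on few UMIs. The largest falls were in the receptor gene Mrgprg (-4.21 ± 0.67), the angiopoietin-like Angptl1 (-3.65 ± 0.30), the glypican Gpc6 (-3.56 ± 0.27), Cpxm2 (-3.54 ± 0.33), the adhesion protein Lsamp (-3.52 ± 0.31) and Tnfrsf19 (-3.26 ± 0.35), with edgeR adjusted p values up to 1.6e-04. Macrophage and dendritic cell markers were higher in 15 of 18, 16 adjusted over the list alone, and lower in 0 (camera adjusted p = 1.1e-06, and adjusted p = 0.164 with an estimated correlation). All 10 mesothelial markers were higher, also over the list alone (camera adjusted p = 2.8e-04, and adjusted p = 0.373 with an estimated correlation), as were 6 of 9 thymic epithelial markers with 1 lower (camera adjusted p = 0.0359, and adjusted p = 0.373 with an estimated correlation), a list that shares the keratin Krt19 with the mesothelial one. Lists that did not pass were glucocorticoid-induced genes (8 higher, 7 lower of 20, camera adjusted p = 0.496), cholesterol synthesis (1 and 3 of 15, camera adjusted p = 0.561) and DNA repair (2 and 3 of 24, camera adjusted p = 0.739). Neither did adipogenesis (3 and 4 of 13, camera adjusted p = 0.766) or myofibroblast and contractile genes (6 and 6 of 14, camera adjusted p = 0.839), whose median of 0.21 was opposite in sign to the test and whose test direction flipped with total-count scaling. Total-count scaling gave 3 myofibroblast genes higher and 6 lower and 2 DNA repair genes higher and 7 lower, and without day 1 replicate 1 the cholesterol list counted 2 and 3. Among other cell types, pericyte and smooth muscle markers (6 higher, 1 lower of 14, camera adjusted p = 0.0508), endothelial (3 and 1 of 6, camera adjusted p = 0.236), adipocyte (1 and 0 of 3, camera adjusted p = 0.243) and thymocyte and T cell markers (0 and 1 of 4, camera adjusted p = 0.496) did not pass. Pericyte and smooth muscle markers passed without day 1 replicate 1 (camera adjusted p = 0.0466), over a range of 0.0207 to 0.373 across the alternatives with camera. Summed over whole marker lists, filtered members included, endothelial markers were at 726 ± 144 CPM against 491 ± 47.7 in untreated samples and adipocyte markers at 95.1 ± 47.6 against 36.04 ± 16.7 (exact permutation adjusted p = 0.0302 for each, n = 5). Schwann cell markers (1 and 2 of 3, camera adjusted p = 0.561) and tuft cell markers (1 and 1 of 3, camera adjusted p = 0.766, direction up) did not pass either. The summed CPM of the 5 tuft cell markers was lower at day 1, at 47.8 ± 12.5 against 74.1 ± 8.16 (exact permutation adjusted p = 0.0302, n = 5). B cell, granulocyte, erythroid and type-2 innate lymphocyte markers had too few members above the filter for a list test; their summed CPM was 4.57, 4.35, 1.41 and 18.9 in untreated samples and 6.97, 30.5, 1.48 and 25.1 at day 1, a difference that passed for granulocyte markers (exact permutation adjusted p = 0.0302, n = 5). The authors' deposited table gave 5227 genes with an adjusted p under 0.05 for this comparison, and 4551 of the 4717 edgeR calls were among them in the same direction. The 50 most abundant genes took 26.6 ± 1.68% of UMIs at day 1 and 22.9 ± 1.16% in untreated samples (exact permutation adjusted p = 0.0452, n = 5). Scaling by total counts moved the median log2 change of all genes by -0.264 and made 29.1% of calls higher, against 49.9% with TMM.

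The second comparison asked which changes were present 3 days after irradiation. p53 targets were the leading group, with Cdkn1a at 1215 ± 208 CPM, 25 members higher and none lower. Of 45 interferon-stimulated genes 21 were higher, and 10 of 24 cell cycle genes were lower, with Mki67 falling from 7.73 ± 1.96 to 0.611 ± 0.570 CPM. Neither list passed with an estimated correlation (camera adjusted p = 0.102 and 0.109). Mmp2, a gelatinase that breaks down matrix, rose from 1834 ± 141 to 4033 ± 665 CPM. In all, edgeR called 1883 of 10207 genes, 939 higher and 944 lower, of which 371 and 334 changed at least 2-fold.

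Of 42 p53 targets, 25 rose and 17 were not called, with 30 higher adjusted over the list alone, and this was the list that passed with both forms of the test (camera adjusted p = 7.9e-16, and adjusted p = 1.0e-05 with an estimated correlation). Cdkn1a changed by 2.64 ± 0.18, Mdm2 by 1.30 ± 0.19, Psrc1 by 2.42 ± 0.25 and Bax, which permeabilises mitochondria in apoptosis, by 1.13 ± 0.12, with edgeR adjusted p values up to 6.6e-05. Cell cycle genes fell in 10 of 24 members and rose in 0, with 14 lower adjusted over the list alone (camera adjusted p = 1.9e-05, and adjusted p = 0.109 with an estimated correlation). The replication enzyme Top2a changed by -2.89 ± 0.37, Mki67 by -3.51 ± 0.46 and Ccnd1 by -2.25 ± 0.23 (edgeR adjusted p values up to 2.3e-05). The log2 change of Mki67 was -4.32 without day 3 replicate 2. Interferon-stimulated genes rose in 21 of 45 and 24 were not called, with 29 adjusted over the list alone (camera adjusted p = 8.4e-13, and adjusted p = 0.102 with an estimated correlation). Irf7 changed by 1.85 ± 0.16, the chemokine Cxcl10 by 1.73 ± 0.22 and Zbp1 by 1.07 ± 0.15 (edgeR adjusted p values up to 5.9e-05). MHC class I genes rose in 6 of 18, the same over the list alone (camera adjusted p = 4.5e-07, and adjusted p = 0.0938 with an estimated correlation). The classical class I genes H2-K1 and H2-D1, whose reads can be shared with related loci, changed by 1.83 ± 0.17 and 1.61 ± 0.16, and Tap1 by 0.95 ± 0.13 (edgeR adjusted p values up to 4.2e-05). Complement genes rose in 7 of 12 and fell in 2 (camera adjusted p = 1.5e-05, and adjusted p = 0.0959 with an estimated correlation). The counts were 9 and 2 when adjusted over the list alone. Cfb changed by 2.02 ± 0.17, C2 by 1.62 ± 0.19 and C4b, counted with the same uncertainty, by 2.68 ± 0.24 (edgeR adjusted p values up to 8.2e-06). Inflammatory cytokines and chemokines rose in 9 of 30, 10 over the list alone (camera adjusted p = 1.5e-04, and adjusted p = 0.257 with an estimated correlation). The membrane-bound chemokine Cx3cl1 changed by 1.09 ± 0.21, the hyaluronan-binding Tnfaip6 by 0.94 ± 0.21 and the neutrophil chemokine Cxcl5 by 2.03 ± 0.42 (edgeR adjusted p values up to 0.00458). Immediate-early and heat-shock genes rose in 10 and fell in 1 of 29 (camera adjusted p = 2.6e-06, and adjusted p = 0.111 with an estimated correlation). Adjustment over the list alone gave 13 and 1. Fosl1 changed by 1.67 ± 0.25, Egr2 by 1.25 ± 0.21 and Jund by 0.80 ± 0.17 (edgeR adjusted p values up to 0.003). NRF2 and antioxidant genes rose in 8 and fell in 1 of 20 (camera adjusted p = 3.7e-04, and adjusted p = 0.151 with an estimated correlation). With adjustment over the list alone they were 10 and 1. Hmox1 changed by 1.70 ± 0.20, sulfiredoxin Srxn1 by 1.01 ± 0.20 and Gclc by 0.96 ± 0.20 (edgeR adjusted p values up to 0.00237). Beside these groups the macrophage and dendritic cell markers were lower in 10 of 18 and higher in 1 (camera adjusted p = 1.7e-05, and adjusted p = 0.181 with an estimated correlation). Counts adjusted over the list alone were 12 and 2. Without day 1 replicate 1, whose spread enters the same model, interferon-stimulated genes counted 29 higher and 1 lower and immediate-early and heat-shock genes 13 and 0, and total-count scaling gave 7 and 2 for NRF2 and antioxidant genes.

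Extracellular matrix genes fell in 15 and rose in 3 of 49 (camera adjusted p = 1.9e-05, and adjusted p = 0.232 with an estimated correlation). Adjusted over the list alone, the counts were 21 and 4. Col8a1 changed by -2.31 ± 0.19, Aspn by -1.94 ± 0.20 and the small proteoglycan Ogn by -1.55 ± 0.19 (edgeR adjusted p values up to 1.1e-05). Col1a1, at 852 ± 163 CPM, lay at the threshold (edgeR adjusted p = 0.05001, 0.00305 to 0.127 over the alternatives) and was called in 7 of 17 alternatives, among them DESeq2 (adjusted p = 0.0335), limma voom (0.00305) and, at a log2 change of -0.75, without untreated replicate 1. Matrix-degrading enzymes and inhibitors rose in 8 and fell in 2 of 24 (camera adjusted p = 0.00906, and adjusted p = 0.181 with an estimated correlation). The counts were 9 and 2 when adjusted over the list alone. Stromelysin-3 gene Mmp11 changed by 2.02 ± 0.21, the membrane protease Mmp14, which activates pro-MMP2, by 1.24 ± 0.14 and Mmp2 by 1.14 ± 0.16 (edgeR adjusted p values up to 4.3e-05). Adventitial fibroblast markers fell in 9 and rose in 1 of 16 (camera adjusted p = 7.9e-04, and adjusted p = 0.181 with an estimated correlation). Adjustment over the list alone gave 10 and 1. Dpp4 changed by -1.83 ± 0.20, Efhd1 by -1.18 ± 0.21 and Pi16 by -0.86 ± 0.17 (edgeR adjusted p values up to 0.00138). Parenchymal markers counted 3 higher and 2 lower of 13 (camera adjusted p = 0.895). With adjustment over the list alone they were 3 and 4. Adipogenesis genes rose in 4 and fell in 1 of 13 (camera adjusted p = 0.0157, and adjusted p = 0.102 with an estimated correlation). Counts adjusted over the list alone were 7 and 1. The lipid droplet protein Plin2 changed by 1.21 ± 0.15, the triglyceride synthase Dgat2 by 1.15 ± 0.20 and Lpl by -1.35 ± 0.23 (edgeR adjusted p values up to 4.9e-04). The list shares Car3, Cfd and Fabp4 with the adipocyte markers, whose summed CPM was 360 in day 3 replicate 5 and 158 in day 3 replicate 2, against 42.5 to 65.6 in the other day 3 libraries. Myofibroblast and contractile genes fell in 7 and rose in 2 of 14 (camera adjusted p = 0.029, and adjusted p = 0.232 with an estimated correlation). Adjusted over the list alone, the counts were 7 and 3. Ccn2, a TGF-β target, changed by -1.42 ± 0.22, calponin Cnn2 by -0.92 ± 0.16 and the activin subunit Inhba by -2.24 ± 0.42 (edgeR adjusted p values up to 0.00101). Fibroblast identity genes fell in 4 and rose in 1 of 19 (camera adjusted p = 0.0198, and adjusted p = 0.265 with an estimated correlation). The counts were 5 and 1 when adjusted over the list alone. Their summed CPM was 70275 ± 3099 (exact permutation adjusted p = 0.0302, n = 5). Pdgfra changed by -0.68 ± 0.16 and Cd34 by -0.53 ± 0.16 (edgeR adjusted p = 0.00615 and 0.022), the Cd34 call being lost without untreated replicate 5 (adjusted p = 0.0508) or day 3 replicate 3 (0.0592), over a range of 0.00171 to 0.0592. With total-count scaling 0 matrix genes were higher and 23 lower, 0 identity genes higher and 6 lower, and 3 parenchymal markers higher and 4 lower.

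Thymic growth and niche factors counted 8 higher and 5 lower of 32 (camera adjusted p = 0.615). Adjustment over the list alone gave 10 and 8. Total-count scaling turned the balance over all genes to 6 higher and 8 lower. Gas6, the ligand of TAM receptor kinases, rose from 304 ± 42.9 to 1212 ± 168 CPM, while the vessel-stabilising ligand Angpt1 changed by -1.22 ± 0.25 and Kitl, the stem cell factor, by -1.04 ± 0.23 (edgeR adjusted p values up to 0.00309). Bmp4 changed by -0.74 ± 0.20 and Cxcl12 by 1.11 ± 0.26 (edgeR adjusted p = 0.0143 and 0.00694), and Fgf7 was at 45.7 ± 4.44 CPM without a call (edgeR adjusted p = 0.984, 0.719 to 0.991 over the alternatives). Type-2 immune mediators counted 4 higher and 1 lower of 12, or 4 and 4 over the list alone, 3 and 4 with total-count scaling, and 4 and 2 without day 1 replicate 1 (camera adjusted p = 0.684, direction up, median 0.02, mean -0.27). Socs1 changed by 1.31 ± 0.21, Cish by 1.21 ± 0.27 and Ccl22, a chemokine for type-2 helper cells, by -5.94 ± 1.00, being at 0 UMIs in 4 of 5 day 3 libraries (edgeR adjusted p values up to 0.00453). Without day 3 replicate 4, which held all day 3 UMIs of Ccl22, its log2 change was -7.69. Macrophage and dendritic cell markers were also lower in 10 of 18 members and higher in 1, and whether Ccl22 fell with RNA of such cells was not tested. Il33 was at 446 ± 45.6 CPM (edgeR adjusted p = 0.778, 0.396 to 0.968 over the alternatives) and Tslp at 6.69 ± 1.64 CPM (edgeR adjusted p = 0.0502, 0.0118 to 0.164), neither called. Tslp was called in 7 of 17 alternatives, among them DESeq2 (adjusted p = 0.0480), limma voom (0.0118) and edgeR at -0.77 without untreated replicate 1 and at -0.82 without day 3 replicate 2.

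The largest day 3 rise among non-overlapping genes was in Mir692-1, at 346 ± 751 CPM, whose reads can be shared with other copies. Day 3 replicate 5 held 1688 CPM of it, and without that library the log2 change was 1.51 in place of 6.64 (edgeR adjusted p = 0.00565 and 0.0271, 0.00565 to 0.336 over the alternatives, above 0.05 without any 1 of untreated replicates 2 to 5). The call was also lost with limma voom, at a log2 change of 3.39 (adjusted p = 0.336), and in edgeR with the replicate block, at 4.035 (adjusted p = 0.155). The epithelial keratins Krt14 (3.95 ± 1.02) and Krt8 (3.52 ± 0.67), the desmosomal Perp (3.49 ± 0.65), the natriuretic peptide Nppc (3.84 ± 0.32) and the G protein subunit Gng13 (3.74 ± 0.62) rose next (edgeR adjusted p values up to 0.0175). The log2 change of Krt14 was 4.88 without untreated replicate 5 and 3.22 without day 3 replicate 4. Falls were largest in Col8a1, Ccnd1, D17H6S56E-5 (-2.03 ± 0.33, reads possibly shared with copies), the actin-binding Marcks (-2.002 ± 0.21), Aspn and the sarcoglycan Sgcd (-1.93 ± 0.21), with edgeR adjusted p values up to 3.7e-04. Beside the keratins, mesothelial markers were higher in 3 of 10, 8 over the list alone (camera adjusted p = 2.3e-05, and adjusted p = 0.232 with an estimated correlation), and thymic epithelial markers in 4 of 9 (camera adjusted p = 0.00192, and adjusted p = 0.181 with an estimated correlation). Thymocyte and T cell markers were lower in 3 of 4 (camera adjusted p = 0.0275, and adjusted p = 0.181 with an estimated correlation), and adipocyte markers passed upward with no member called over all genes and 3 of 3 over the list alone (camera adjusted p = 0.0349, and adjusted p = 0.232 with an estimated correlation). Unfolded protein response genes, 3 higher and 1 lower of 20, or 3 and 3 with total-count scaling, did not pass (camera adjusted p = 0.819, direction up, median -0.02), nor did DNA repair, glucocorticoid-induced, cholesterol, endothelial, Schwann, pericyte or tuft cell lists (camera adjusted p from 0.18 to 0.895). The summed CPM of tuft cell markers was 40.7 ± 8.07, again lower than in untreated samples, while the test of the 3 above the filter pointed up, and Malat1, a nuclear non-coding RNA, was at 23.05 ± 5.58 CPM of total counts against 45.2 ± 10.9 (exact permutation adjusted p = 0.0302 for each, n = 5). The authors' deposited table gave 2190 genes under 0.05, which included 1807 of the 1883 edgeR calls in the same direction. Total-count scaling moved the median log2 change by -0.12 and made 31.4% of calls higher, against 49.9%.

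**Figure D2:**
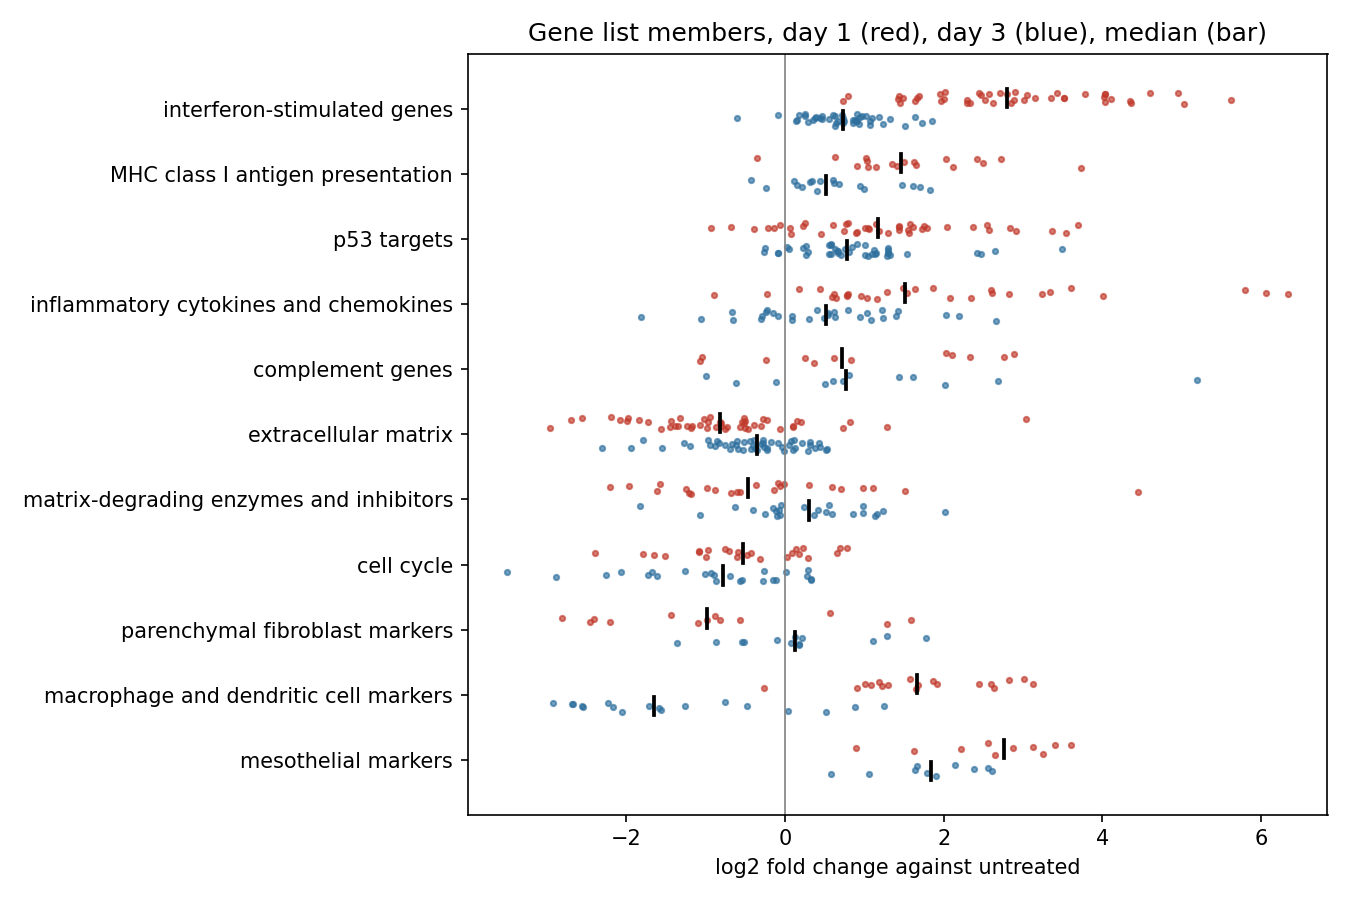
Log2 change against untreated (x axis) of each tested member of 11 gene lists (y axis), at day 1 in red and day 3 in blue, with the list median as a black bar. Interferon-stimulated genes had medians of 2.80 and 0.74, p53 targets 1.17 and 0.79, and macrophage markers 1.66 and -1.65.

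The third comparison, day 3 against day 1, tested the difference between the other 2 directly. Interferon-stimulated genes and macrophage markers were lower at day 3, and Cdkn1a did not differ by a detectable amount, at 1467 ± 316 and 1215 ± 208 CPM (edgeR adjusted p = 0.229). Isg15 fell from 5181 ± 806 to 381 ± 117 CPM and Saa3 from 26362 ± 8056 to 805 ± 201 CPM, while Mmp2 rose from 1205 ± 233 to 4033 ± 665 CPM. Of 19 fibroblast identity genes 12 rose and of 49 matrix genes 24, though neither list passed with an estimated correlation (camera adjusted p = 0.154 and 0.304). edgeR called 3335 genes, 1644 higher and 1691 lower at day 3, of which 601 and 650 changed at least 2-fold.

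Of 45 interferon-stimulated genes, 43 fell, also over the list alone (camera adjusted p = 9.4e-34, and adjusted p = 0.0191 with an estimated correlation). Zbp1 changed by -2.96 ± 0.16, Isg15 by -3.77 ± 0.21 and Irf7 by -2.75 ± 0.17 (edgeR adjusted p values up to 1.9e-10). Inflammatory cytokines and chemokines fell in 16 and rose in 1 of 30, the same over the list alone (camera adjusted p = 1.2e-06, and adjusted p = 0.236 with an estimated correlation). Saa3 changed by -5.03 ± 0.54, the chemokine Ccl3 by -5.06 ± 0.60 and Cx3cl1 by 1.98 ± 0.23 (edgeR adjusted p values up to 6.5e-06). MHC class I genes fell in 11 and rose in 1 of 18 (camera adjusted p = 3.1e-06, and adjusted p = 0.0574 with an estimated correlation). With adjustment over the list alone they were 13 and 1. Nlrc5 changed by -2.26 ± 0.18, Tap1 by -1.55 ± 0.13 and Psmb8 by -1.80 ± 0.15 (edgeR adjusted p values up to 1.4e-08). Beside these immune groups, all 18 macrophage and dendritic cell markers were lower (camera adjusted p = 2.6e-15, and adjusted p = 0.0457 with an estimated correlation), their summed CPM going from 1461 ± 270.3 to 225 ± 50.2, and granulocyte markers went from 30.5 ± 18.8 to 6.88 ± 3.13 (exact permutation adjusted p = 0.0302 for each, n = 5). Unfolded protein response genes fell in 10 and rose in 1 of 20 (camera adjusted p = 2.8e-04, and adjusted p = 0.0457 with an estimated correlation). Counts adjusted over the list alone were 11 and 1. Calr changed by -1.22 ± 0.14, Pdia6 by -0.96 ± 0.13 and Sdf2l1 by -2.08 ± 0.29 (edgeR adjusted p values up to 1.5e-05). Immediate-early and heat-shock genes fell in 8 of 29, the same over the list alone (camera adjusted p = 0.00602, and adjusted p = 0.344 with an estimated correlation). Ier3 changed by -1.25 ± 0.21, the Hsp70 gene Hspa1a, nearly identical to Hspa1b, by -1.43 ± 0.27 and Hsph1 by -1.31 ± 0.27 (edgeR adjusted p values up to 0.00101). p53 targets fell in 13 and rose in 5 of 42 (camera adjusted p = 0.0259, and adjusted p = 0.0574 with an estimated correlation). Adjusted over the list alone, the counts were 14 and 5. The death-domain protein Pidd1 changed by -2.16 ± 0.30, Mdm2 by -1.27 ± 0.18 and Dcxr by -1.07 ± 0.18 (edgeR adjusted p values up to 1.1e-04). The unfolded protein response counted 11 lower and 2 higher and immediate-early and heat-shock genes 10 and 1 without day 1 replicate 1.

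Parenchymal fibroblast markers rose in 10 and fell in 1 of 13, the same over the list alone (camera adjusted p = 5.9e-06, and adjusted p = 0.0574 with an estimated correlation). Sparcl1 changed by 2.11 ± 0.19, Smoc2 by 1.94 ± 0.19 and the methyltransferase Inmt by 3.74 ± 0.38 (edgeR adjusted p values up to 2.0e-06). Extracellular matrix genes rose in 24 and fell in 3 of 49 (camera adjusted p = 7.7e-06, and adjusted p = 0.304 with an estimated correlation). The counts were 25 and 3 when adjusted over the list alone. Col14a1 changed by 2.05 ± 0.15, the collagen-degrading cathepsin Ctsk by 1.71 ± 0.18 and tenascin Tnc, a glycoprotein of wounds, by -4.23 ± 0.37 (edgeR adjusted p values up to 3.2e-07). Fibroblast identity genes rose in 12 and fell in 1 of 19 (camera adjusted p = 1.4e-04, and adjusted p = 0.154 with an estimated correlation). Adjustment over the list alone gave 13 and 2. Pdgfra changed by 0.79 ± 0.17 and Cd34 by 1.05 ± 0.16 (edgeR adjusted p values up to 0.00106). Matrix-degrading enzymes and inhibitors rose in 10 and fell in 2 of 24 (camera adjusted p = 0.00176, and adjusted p = 0.127 with an estimated correlation). With adjustment over the list alone they were 12 and 3. Mmp11 changed by 2.90 ± 0.24, Mmp2 by 1.74 ± 0.16 and Timp2 by 1.86 ± 0.18 (edgeR adjusted p values up to 6.5e-08). Beside these fibroblast groups, the summed CPM of identity genes was 70275 ± 3099 at day 3 and 41199 ± 9358 at day 1 (exact permutation adjusted p = 0.0302, n = 5). Without day 1 replicate 1 the matrix list counted 23 higher and 6 lower, matrix-degrading enzymes and inhibitors 12 and 4 and identity genes 11 and 2, and with total-count scaling the enzymes counted 12 and 1 and the growth factors 13 and 1. Thymic growth and niche factors rose in 13 and fell in 3 of 32 (camera adjusted p = 0.0493, and adjusted p = 0.236 with an estimated correlation). Counts adjusted over the list alone were 13 and 4. The list's call was lost with total counts (camera adjusted p = 0.0804) or without day 1 replicate 1 (0.102), over a range of 0.0482 to 0.237 across the alternatives with camera. Sfrp1 changed by 1.91 ± 0.20, Igf1 by 1.79 ± 0.19, Bmp4 by 1.46 ± 0.22 and Fgf7 by 0.69 ± 0.20 (edgeR adjusted p values up to 0.0107). Cell cycle genes fell in 4 of 24, 3 over the list alone, without passing (camera adjusted p = 0.152), among them the helicase subunit Mcm5 at -1.58 ± 0.31, Tubb5 at -0.68 ± 0.15 and Top2a at -1.90 ± 0.43 (edgeR adjusted p values up to 0.00178). Type-2 immune mediators fell in 4 of 12, 6 over the list alone (camera adjusted p = 0.16), including Socs1 at -0.97 ± 0.21, the IL-33 receptor gene Il1rl1 at -1.41 ± 0.37 and Ccl8 at -1.02 ± 0.34 (edgeR adjusted p values up to 0.0305). Of the type-2 mediators, 2 were called lower without day 1 replicate 1, and 2 with total-count scaling. Ccl8 lost its call without any 1 of day 1 replicates 1, 2, 4 and 5 or day 3 replicates 2, 4 and 5 (edgeR adjusted p from 0.0517 to 0.0796). It was also lost with total counts (0.0592) and with the replicate block (0.0878), over a range of 1.2e-04 to 0.0878. Cxcl12, not called, passed without day 1 replicate 1 at a log2 change of -0.41 (edgeR adjusted p = 0.0486, 0.0486 to 0.974 over the alternatives).

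Among non-overlapping genes, the largest rises from day 1 to day 3 were in Mrgprg (5.28 ± 0.65), the cytochrome genes Cyp2e1 (4.44 ± 0.46) and Cyp2f2 (3.09 ± 0.35), Inmt, Gpc6 (3.13 ± 0.27) and the neurotrophin receptor Ngfr (3.13 ± 0.52), with edgeR adjusted p values up to 2.4e-04. The largest falls were in Gpbar1 (-6.67 ± 0.48), Slfn4 (-6.19 ± 0.58), the G protein regulator Rgs1 (-5.83 ± 0.75), the ribonuclease Ear1, one of a family of near copies (-5.31 ± 0.63), the chemokine Ccl4 (-5.15 ± 0.75) and Saa3, with edgeR adjusted p values up to 8.8e-05. All 18 macrophage and dendritic cell markers were lower in this comparison too, and whether the RNA of these genes came from such cells was not tested. Leaving out 1 library gave Ngfr 3.86 (day 1 replicate 3), Slfn4 -6.88 (day 3 replicate 4) and Ear1 -4.65 (day 1 replicate 2). Day 3 libraries held 0 to 0.621 CPM of Gpbar1 and 0 to 1.39 of Slfn4, so the sizes of their falls rest on few UMIs. Adipogenesis, adventitial, myofibroblast, Schwann, endothelial, thymocyte, DNA repair, thymic epithelial, pericyte and mesothelial lists did not pass (camera adjusted p from 0.0728 to 0.635), and complement, cholesterol, tuft, glucocorticoid, NRF2 and adipocyte lists were at 0.898 to 0.998. Summed CPM was lower at day 3 than at day 1 for endothelial markers, 464 ± 87.8 against 726 ± 144, and pericyte and smooth muscle markers, 473 ± 64.8 against 708 ± 156 (exact permutation adjusted p = 0.0452 for each, n = 5). In the last 5 of these 6 lists the median, mean and test differed in sign, as for adipocyte markers with a median of 2.31 and a camera direction downward. The authors' deposited table gave 3618 genes under 0.05, which included 3204 of the 3335 edgeR calls in the same direction. With total-count scaling the median log2 change moved by 0.144 and 65.7% of calls were higher, against 49.3%.

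Across both times, 652 genes were called higher and 682 lower at day 1 and day 3. Independent lists of these lengths would share 216.6 and 218.5 genes. Simulated unchanged groups against the same controls shared 0, but they had a mean of only 0.05 calls higher and 0 lower per comparison. Their shared count is thus no baseline. With the untreated libraries split between the 2 comparisons, 101 to 379 genes were higher and 107 to 424 lower in both over 20 splits. Log2 changes correlated at 0.641 across genes, which are not independent replicates, against 0.514 in the simulation, and their covariance was 0.394 against 0.0351, a difference of 0.358. With the untreated libraries split, the correlation was 0.489 to 0.594 and the covariance 0.321 to 0.416. Of the 2355 genes higher at day 1, 1343 were lower at day 3 than at day 1, and 1107 of these were not called against untreated at day 3. Of the 2362 genes lower at day 1, 1252 were higher at day 3 than at day 1, and 1009 of these were not called at day 3. In the opposite direction at day 3 were 22 of the genes higher at day 1 and 34 of those lower. Genes called at day 3 that moved between day 1 and day 3 and were not called at day 1 numbered 143 higher and 110 lower.

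In the GRCm38 (mm10) annotation, Isg15 lies on chromosome 4 from 156199424 to 156200818, Saa3 on chromosome 7 from 46711998 to 46715700, Cdkn1a on chromosome 17 from 29090976 to 29100727 and Mmp2 on chromosome 8 from 92827291 to 92853420. Cd34 lies on chromosome 1 from 194938819 to 194961279, Pdgfra on chromosome 5 from 75152292 to 75198215 and Il33 on chromosome 19 from 29925114 to 29960718. All 7 are annotated as protein coding genes, and MARS-seq reads count toward their 3' ends.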

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

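The coherence, epithelial ratio, identity spread and scaling tests in this part were chosen only after the results were seen, while the thinning, covariate and split tests were written down beforehand. The effects at day 1 and day 3 differed in 3335 genes called by edgeR in day 3 against day 1, which tests the difference directly. A single library stood far from the other 4 of its group, by Dixon's ratio of its gap to the group's range, in 40 of 438 groups of 5 values over 127 genes and the library measures. Chance alone gives about 1 in 20 groups, or 21.9.

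Untreated replicate 1 was highest for Psmb8 (ratio 0.716, 238 against 156 to 179 CPM), Mir692-1 (ratio 0.831, 4.25 against 3.23 to 3.40 CPM), H2-K1 (ratio 0.812, 1707 against 1007 to 1139 CPM), H2-D1 (ratio 0.857, 2684 against 1640.3 to 1789 CPM) and Inmt (ratio 0.771, 812 against 609 to 656 CPM). Untreated replicate 1 was lowest for Mmp2 (ratio 0.761, 1588 against 1859 to 1945 CPM) and Kitl (ratio 0.781, 16.2 against 26.3 to 29.1 CPM). Untreated replicate 2 was highest for Igf1 (ratio 0.784, 247 against 154 to 174 CPM) and Ccl4 (ratio 0.757, 8.89 against 0 to 2.16 CPM). Untreated replicate 5 was highest for Lcn2 (ratio 0.914, 183 against 33.9 to 46.8 CPM), Saa3 (ratio 0.878, 1077 against 150.1 to 263 CPM), Egr2 (ratio 0.755, 54.9 against 39.1 to 42.99 CPM), Krt14 (ratio 0.796, 5.53 against 0.719 to 1.70 CPM), Ccn2 (ratio 0.798, 334 against 155 to 191 CPM) and Cyp2e1 (ratio 0.713, 17.02 against 6.80 to 9.74 CPM). Day 1 replicate 1 was highest for Hspa1a (ratio 0.891, 12532 against 4448 to 5332 CPM) and Hsph1 (ratio 0.769, 499 against 377 to 405 CPM). Day 1 replicate 1 was lowest for Il33 (ratio 0.735, 189 against 433 to 521 CPM). Day 1 replicate 2 was highest for Ear1 (ratio 0.739, 57.1 against 6.56 to 19.8 CPM). Day 1 replicate 3 was highest for Cxcl16 (ratio 0.748, 245 against 156 to 178 CPM). Day 1 replicate 5 was highest for Aspn (ratio 0.722, 103 against 34.6 to 53.6 CPM), Sparcl1 (ratio 0.754, 434 against 196 to 255 CPM), Bmp4 (ratio 0.899, 89.2 against 36.2 to 41.6 CPM), Tslp (ratio 0.723, 15.1 against 5.94 to 8.48 CPM) and Marcks (ratio 0.778, 47.2 against 14.8 to 22.05 CPM). Day 3 replicate 1 was lowest for Jund (ratio 0.716, 908 against 1322 to 1486 CPM). Day 3 replicate 2 was highest for Mki67 (ratio 0.832, 1.62 against 0.279 to 0.505 CPM). Day 3 replicate 3 was highest for Cx3cl1 (ratio 0.810, 147 against 80.4 to 93.1 CPM) and Cnn2 (ratio 0.754, 127 against 69.6 to 83.7 CPM). Day 3 replicate 3 was lowest for Tnfaip6 (ratio 0.771, 924 against 1201 to 1284 CPM). Day 3 replicate 4 was highest for Ccl22 (ratio 1.000, 0.557 against 0 to 0 CPM). Day 3 replicate 4 was lowest for Cxcl12 (ratio 0.782, 384 against 427 to 439 CPM). Day 3 replicate 5 was highest for Mir692-1 (ratio 0.997, 1688 against 6.69 to 12.4 CPM) and Lyz2 (ratio 0.889, 11.3 against 4.54 to 5.29 CPM). Genes detected were lowest in untreated replicate 1 (ratio 0.802, 12015 against 12355 to 12439), day 1 replicate 1 (0.856, 11180 against 12252 to 12433) and day 3 replicate 3 (0.801, 12284 against 12513 to 12570). The 50 most abundant genes took 24.9% of UMIs in untreated replicate 1 against 21.9% to 22.8% in the others (ratio 0.714), and ribosomal protein genes took 7.16% in untreated replicate 5 against 8.75% to 9.30% (ratio 0.743). Summed CPM of fibroblast identity genes was lowest in day 1 replicate 1 (ratio 0.759, 25010 against 42578 to 48150).

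Macrophage and dendritic cell markers were higher at day 1 in cells gated as CD45-negative, with C1qb, a complement subunit of macrophages, going from 26.4 ± 21.7 to 91.6 ± 38.05 CPM and the lysosomal protein Cd68 from 10.5 ± 4.18 to 65.04 ± 13.95. Lower depth of the day 1 libraries was argued against. Their total UMIs did not differ by a detectable amount from untreated ones (exact permutation adjusted p = 0.777, n = 5). In thinned counts 8 of 14 markers tested were still called higher. Thinning also removes power, so markers that lost their call there do not bear on depth. RNA of macrophages or monocytes in the sorted samples may account for the markers and remained open. Their deviations from the group means had a mean correlation of 0.329 against 0.0725 at the 95th percentile of random lists. Process lists also lay above 0.0725, with 0.298 for inflammatory cytokines and chemokines and 0.236 for matrix genes. The correlation thus could not tell such RNA from genes regulated together. Lyz2, abundant in many macrophages, was at 43.4 ± 43.4 and 33.2 ± 12.1 CPM without a call. With the markers' level as a covariate, the median log2 change of interferon-stimulated genes was 2.604 against 2.801, and 33 of 45 were called. Calls over all genes went from 4717 to 954. The covariate's slope rests on differences within groups, so this argued only against macrophage RNA of like content in all groups as the source of the rise. It could not tell macrophage RNA richer in these transcripts at day 1 from a response to irradiation within the fibroblasts, and both remained possible.

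Mesothelial markers were higher at day 1 in cells gated as positive for CD34 and PDGFRα, such as mesothelin, Msln, at 52.5 ± 35.4 and 544 ± 302 CPM and the keratin Krt19 at 27.7 ± 19.9 and 320.3 ± 186 CPM. RNA of thymic epithelial cells was argued against as their source, since epithelial markers other than Krt8, Krt18 and Krt19 summed to 0.072 of the mesothelial sum at day 1 (0.0605 to 0.0827 per library). RNA of mesothelial cells in the sorted samples may explain them and remained open, with a mean correlation of deviations of 0.76 against 0.114 at the 95th percentile of random lists. Genes regulated together would also exceed random lists, so the correlation could not decide this. Expression of these genes by irradiated fibroblasts was not tested, and the bulk libraries could not tell it from a mixture.

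Fibroblast identity genes were lower at day 1, with the proteoglycan Dcn going from 15910.2 ± 764 to 6381 ± 1965 CPM. Cochran's Q over its degrees of freedom was 25.1 (15 without Ly6a), and the log2 changes ran from -1.84 for Lum to 1.92 for Ly6a, with Pdgfrb also higher. This argued against replacement of fibroblasts by cells without these transcripts as the only cause. Cells that express some of the genes would also give unequal changes, so a lower share of fibroblasts was not excluded. The scaling of the libraries was argued against as the only cause by the same value, since a scaling factor moves every gene of a library by 1 common amount. An effect of irradiation on these genes may remain, and a part from a changed mixture of cells or from the scaling was not excluded by the value of 25.1.

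Other divisions of the 10 libraries of a comparison into 5 and 5 were drawn 100 times, the real one included. For genes, only the real division of each 100 reached 4717, 1883 and 3335 calls, with highest other values of 1821, 272 and 200. This argued against a random assignment of libraries to groups as the source of the calls. Every other division mixes the real groups, which adds to the spread within them and lowers their counts. A batch or an origin shared by the libraries of a group was not tested by these divisions. For lists, the real division passed 14 at day 1 and 19 at day 3, with highest other values of 15 and 19. At least as many passed in 3 and 2 of the 100 divisions, the real one included. Chance was thus argued against for these numbers but not excluded. For day 3 against day 1, chance remained open for the number of 12 lists, with a highest other value of 14 and 9 divisions at least as high. Other divisions gave a median of 7, 7 and 4 lists, against 0 genes in each comparison. Groups of 5 cannot be mixed evenly, so every other division also kept part of the real difference. Its list counts were therefore no baseline without an effect, and how many lists pass by chance was not shown. The argument against chance at day 1 and day 3 covers the number of lists, not any 1 list.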

How the results depend on the processing

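The list tests without day 1 replicate 1 were the alternative chosen only after the data were seen. In no setting was a called gene called in the opposite direction. Of the called genes that the naming rule gives or the text adds, 83 of 83 at day 1, 70 of 78 at day 3 and 76 of 77 between days 3 and 1 kept direction and call in every setting run for single genes, up to 17. Thinning, glmTreat and only the compared groups were run for counts alone. The 4717 genes of day 1 went to 1866 with thinned counts and 2055 with glmTreat, the 1883 of day 3 to 344 and 284, and the 3335 of day 3 against day 1 to 1189 and 965, as fewer counts and a stricter threshold give. With limma voom, day 3 had 3289 calls. Its quality weights were lowest for day 1 replicate 1, at 0.253, and edgeR without the day 1 libraries called 2541 genes at day 3. Whether the spread at day 1 held down the main count of 1883 was not tested. Other counts stayed within 1.5 times, at 4784, 2127 and 3457 with DESeq2, 4704, 1876 and 3336 with RLE, 5150, 2102 and 3508 with total counts, 5304, 2080 and 3590 without a filter, and 4044, 2541 and 2872 with only the compared groups. Slfn4, Mki67, Ccl22 and Ccl3 had no value with at least 10 counts in 5 libraries, nor Mir692-1 with DESeq2. Leaving out each library in turn gave 4238 to 4828, 1299 to 2071 and 2804 to 3547 calls.

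Replicate numbers were not taken to pair the samples, since same-numbered libraries deviated together at a correlation over 0.1 in 2 of 5, 2 of 5 and 0 of 5 pairs for untreated with day 1, untreated with day 3 and day 1 with day 3. Only 1, 2 and 0 libraries correlated best with their own number, so not every sample did. The replicate block gave 4511, 1596 and 3102 genes and 15, 19 and 12 lists, against 14, 19 and 12 lists without it. Col1a1, not called without the block, passed with it at day 1 and day 3 (edgeR adjusted p = 0.0230 and 0.0242). Calls lost with the block included Mir692-1 at day 3 (edgeR adjusted p = 0.155) and Ccl8 for day 3 against day 1 (0.0878). The list gained at day 1 was that of pericyte and smooth muscle markers (camera adjusted p = 0.0438). Under the block Il33 at day 1 was -0.0163, Lyz2 at day 1 was 0.14, and the lists of tuft cell markers at day 3 and adipocyte markers between days 3 and 1 had camera adjusted p of 0.994 and 0.954 in the reversed direction.

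With an estimated correlation the lists past 0.05 went from 14 to 4, 19 to 1 and 12 to 3. With fry day 1 had 24. fry asks whether members changed at all, and camera whether they changed more than other genes. At day 1, 46.21% of all genes were called, so the counts of fry and camera answer different questions. How far this accounts for the 24 was not tested. Without day 1 replicate 1 the numbers were 16, 19 and 11. Splitting the untreated libraries took the 1334 genes called alike at both times to 208 at the lowest and 782 at the highest, with fewer libraries per comparison.

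Results that reversed had not been called, and the cause was not tested. With total counts Il33 was -0.24 at day 1 and -0.0164 at day 3 and Fgf7 -0.11 at day 3, and the myofibroblast list had a camera adjusted p of 0.938 at day 1. With limma voom Il33 was -0.0132 for day 3 against day 1 and Lyz2 0.77 at day 1. Leaving out 1 library gave Il33 -0.0737 to 0.213 at day 1 and -0.11 to 0.17 for day 3 against day 1, Fgf7 -0.0662 to 0.0570 at day 3, Lyz2 -0.57 to 0.38 at day 1 and Col1a1 -0.35 to 0.0677 for day 3 against day 1. With fry, cholesterol synthesis and adipocyte markers reversed for day 3 against day 1 (fry adjusted p = 0.979 and 0.900). Without day 1 replicate 1, tuft cell markers at day 3 (camera adjusted p = 0.824) and glucocorticoid, NRF2 and adipocyte lists for day 3 against day 1 (0.964, 0.811 and 0.811) reversed. Thinned to 740169 UMIs, 7633 genes passed the filter.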

Other observations

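All tests in this part, on 1 list of lysosomal and 2 of imprinted genes, were chosen only after the results were seen, as were the genes named. Lysosomal enzyme and membrane protein genes, which serve the breakdown of proteins and lipids, were called higher more often than lower at day 3. Of 47 tested, 15 were called higher and 1 lower against untreated by edgeR, and 15 and 2 adjusted over the list alone. The phospholipase Pla2g15 went from 61.9 ± 6.16 to 116 ± 24.03 CPM, the heparan sulfate hydrolase Naglu from 72.6 ± 11.2 to 144 ± 25.6 and the cystine exporter Ctns from 12.99 ± 3.54 to 29.8 ± 3.87 (edgeR adjusted p values up to 0.00183). The hypothesis that these genes rose together as a set was tested with camera and an estimated correlation (p = 0.0112), and it remained open. Against day 1, 27 were higher and 3 lower (camera p = 0.00798 with an estimated correlation), and at day 1 against untreated 8 were higher and 16 lower (camera p = 0.306). Macrophage markers, which also come from cells rich in lysosomes, had a lower summed CPM at day 3 than in untreated samples, 225 ± 50.2 against 650.4 ± 317 (exact permutation adjusted p = 0.0302, n = 5).

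Imprinted genes, expressed from a single parental copy in at least some tissues and many of them tied to growth, included some of the deeper falls at day 1. The maternally expressed RNA H19 went from 746 ± 178 to 118 ± 30.4 CPM and was at 855 ± 254 CPM at day 3, and the paternally expressed Mest from 105 ± 15.5 to 17.9 ± 6.66 and 141 ± 39.6 CPM. Day 1 against untreated, the log2 changes were -2.67 ± 0.23 and -2.61 ± 0.24, and day 3 against day 1 2.86 ± 0.23 and 3.04 ± 0.24 (edgeR adjusted p values up to 2.2e-08). The hypothesis that paternally expressed imprinted genes fell together as a set was tested with camera and an estimated correlation (p = 0.293), and it remained open, with 6 of 10 tested members lower and 2, Impact and Mcts2, higher at day 1. Of 11 maternally expressed genes tested, 5 were lower and 2 higher at day 1 (camera p = 0.133 with an estimated correlation). The lower ones included Dcn, which is also in the fibroblast identity and matrix lists. Expression by parental copy was not measured in these cells.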
